A study of Caenorhabditis elegans with 83 samples.

How the data were processed

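The series used auxin-inducible degradation in whole L2/L3 Caenorhabditis elegans, in which a protein carrying a degron tag is removed after auxin is added. The 83 samples comprised 72 ChIP-seq, 5 Hi-C and 6 RNA-seq samples. Strain CA1200 was the auxin-treated control, strain JK05 was used to deplete the cohesin subunit SMC-3, and strain JK06 was used to deplete WAPL-1, the cohesin release factor. A further strain, HW04, was sampled with and without auxin, and its degron target is not given in the sources used here. ChIP was done after 1 h of auxin and RNA-seq after 4 h. Worms were grown for 24 h at 22 °C.

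Peak lists and RNA comparison tables were the files used. The 21 peak lists comprised 6 sets that the authors combined over replicate libraries, 1 list called on averaged libraries and 14 lists of single libraries. Hi-C, SMC-1, GFP and 8WG16 ChIP and the input libraries were not analysed here, since no processed table for them was used. A further 8 deposited files were not used, being summit lists that repeat columns of the peak lists and a list of file names. The submitters' processing notes name Bowtie2 2.4.2, SAMtools 1.11, deepTools 3.5.0, MACS2 2.1.1 and MACS3 for ChIP-seq. They name HISAT2 2.2.1, HTSeq 0.13.5, Cufflinks 2.2.1 and DESeq2 1.30.0 for RNA-seq, and Juicer 1.5.7 for the Hi-C that was not analysed here.

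In the deposited peak lists the authors gave each peak a score, which is 10 times the −log10 q value as a whole number. The deposited lists also hold the fold enrichment (ratio of ChIP over input) at the summit, the −log10 p and the −log10 q of each peak. The deposited RNA tables hold, per the file headers, the log2 fold change of a depletion strain over CA1200, its standard error on the log2 scale, the Wald statistic (a score equal to their quotient), the p-value and the adjusted p-value of the authors' DESeq2 fit, and the mean normalized count over both strains. Each RNA group had 2 libraries. Read counts per library are not in the files, so sequencing depth is unknown, and the deposited standard errors are the measure of precision. For the X chromosome share of a peak set, exact Clopper-Pearson 95% intervals over peaks were computed, and they cover counting error only.

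The labels state build ce10 for 38 samples and no build for the other 45, and none for the gene coordinates of the RNA tables. Peak summits and gene starts were therefore compared near the chromosome ends, where builds drift apart. This was done for 8 of the 21 peak lists. The summits of those other than the control SMC-3 set lay within 13 bp (median per chromosome) of the control SMC-3 summits. Summits lay on the upstream side of gene starts on both strands, and the offset between the strands' midpoints was at most 81.3 bp, on chromosome IV. There the offset had the same sign in all 8 lists, and its cause was not tested. Genes and peaks were treated as sharing coordinates on that basis. The plan had tied the comparison of genes near gained peaks to an annotation stated to be ce10, which was not given, so that comparison departs from the plan and rests on this check. The gene at a peak is the one with the nearest start in the RNA tables.

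The combined SMC-3 set of strain JK06 and the combined PQN-85 set of strain JK06 are attached to other samples in the deposit, and were assigned by the library names inside their peak names. In strain HW04, 4 SMC-3 lists carry peak names that state the opposite auxin condition to their labels. The labels were kept for the main values.

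Peak sets were compared by the share of peaks overlapped by at least 1 bp. That share was set against 1000 circular shifts of the other set within each chromosome in a one-sided permutation test by shifts whose smallest p is 0.001. Peak numbers in strain HW04 were compared on the log2 scale by two-sided exact permutation tests of 2 against 2 libraries, for which the smallest p is 0.333. Called genes are those with the authors' adjusted p under 0.05. The 20 gene lists were tested with Fisher's exact test per direction, and by the two-sided percentile of the list's median log2 fold change among 10000 random lists matched on mean expression in 20 bins (smallest p 2e-04). Both were adjusted over the lists by the Benjamini-Hochberg method. Median log2 fold changes of X-linked and autosomal genes, and of genes near peak classes, were compared by two-sided permutation over genes with 100000 resamples. Genes are not independent replicates, so these tests describe the libraries at hand. Overlap between the depletions was set beside 100 simulations of unchanged strains that share a control.

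The lists, main tests and alternatives were fixed before the data were examined, except for that departure and where the text names a later choice. The tests of explanations in the closing sections were not part of that plan. Named genes were smc-3, wapl-1, smc-1 (now him-1), scc-1, pqn-85 (now scc-2), mau-2 and skn-1. To these were added up to 10 called genes per direction with the largest changes, a mean normalized count of at least 50 and a symbol of the 3-letter class, and up to 4 members per list with the smallest adjusted p. Named peaks were the 3 with the highest scores in each class of each overlap comparison. Older symbols without a current match were not tested.

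Alternatives covered a reciprocal overlap of 50%, the higher-scoring part of each set, sets without X, single lists, covered bases, left-out replicates, an adjusted p under 0.01, a 2-fold minimum, a mean normalized count of at least 10, centred fold changes and a distance of 500 bp. The overlap test was tested on simulated data, in which 30.2% planted shared peaks were recovered as 30.2% beyond chance. At the deposited standard errors, 69% of simulated 4-fold changes were called in the SMC-3 table and 32% in the WAPL-1 table. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.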

Results

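Cohesin was mapped by ChIP-seq of its core subunit SMC-3, and its loader by ChIP-seq of PQN-85, the worm NIPBL-type protein, in L2/L3 worms after 1 h of auxin. The control, SMC-3 depletion and WAPL-1 depletion conditions each had 1 combined peak set per antibody, made by the authors over replicate libraries. Comparisons of these sets have no replicate error. WAPL-1 depletion also had single SMC-3 lists of replicates 3 and 4 and a PQN-85 list called on averaged libraries. Strain HW04 had SMC-3, PQN-85 and H4K20me1 peak lists for 2 libraries with and 2 without auxin. Gene expression was measured by RNA-seq after 4 h of auxin in 2 libraries per strain, and was available as the authors' comparison of each depletion with the control. Read counts per library were not given, so depth is unknown. The depletion strains were compared with strain CA1200, not with their own samples without auxin. Depletion and other differences between strains cannot be told apart in these comparisons.

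The SMC-3 peak set shrank on depletion of SMC-3, which addresses whether the degron took away the ChIP target. The control set held 6290 SMC-3 peaks over 5.28 Mb and the SMC-3 depletion set held 361 over 0.356 Mb. Of the control peaks, 261 (4.15%) were overlapped by a peak left after depletion, against 0.652% on average for shifted sets (one-sided permutation p by shifts = 0.001, the smallest the shifts allow). The control peaks without a counterpart included the highest-scoring control peak, on chromosome III from 354056 to 359981 (ce10), with its summit at −6372 bp from the start of gei-4. Another lay on chromosome III from 13069305 to 13073012, with its summit at −71 bp from the start of Y39E4B.6 (negative distances are upstream). Among those kept, the peak on chromosome II from 5844405 to 5845317 lay within nep-25, and 1 on chromosome II from 5543237 to 5544475 lay at −1829 bp from hlh-27. Conversely, 259 of the 361 peaks left (71.7%) coincided with a control peak.

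Depletion of WAPL-1, which releases cohesin from chromatin, left the number of SMC-3 peaks near that of the control, with part of the sites called in 1 of the sets only. The set held 6107 peaks over 4.85 Mb. It overlapped 4276 control peaks (68.0%), against 9.76% for shifted sets (one-sided permutation p by shifts = 0.001), while 2014 control peaks had no counterpart and 1710 peaks were present in WAPL-1 depletion only. Between libraries of 1 condition the shares were 68.6% (longer list) and 90.8% (shorter list) for replicates 3 and 4 of WAPL-1 depletion, 79.3% and 74.2% for HW04 labelled auxin and 74.3% and 78.8% for HW04 labelled no auxin. Whether peaks present in 1 set only are due to the depletion was not tested. The highest-scoring of the latter lay on chromosome X from 15590231 to 15591026, at −308 bp from the start of gas-1, which encodes a subunit of mitochondrial complex I. Others lay on chromosome I from 5281384 to 5282238, at −348 bp from dhs-1, and on chromosome V from 11933119 to 11933808, at −124 bp from F58H1.3. The highest-scoring peaks present only in the control lay within genes or farther from a gene start, as on chromosome IV from 2992951 to 2993897 within Y54G2A.26 and on chromosome V from 10721074 to 10723908 within T28B11.1. The share of summits within 500 bp of a gene start was 42.0% in WAPL-1 depletion, 34.6% in the control and 22.99% in SMC-3 depletion, against 17.4%, 17.5% and 17.3% for shifted peaks. The median peak width was 572 bp in WAPL-1 depletion and 589 bp in the control, a ratio of 0.971. The single lists of replicates 3 and 4 held 8876 and 6782 peaks with median widths of 499 and 496 bp, while the combined set drew on 4 libraries.

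In the control, PQN-85 and SMC-3 shared most of their sites. Of 5385 PQN-85 peaks, 3972 (73.8%) were overlapped by an SMC-3 peak, against 9.18% for shifted sets (one-sided permutation p by shifts = 0.001). The highest-scoring shared peak lay on chromosome III from 1923076 to 1924243 within pqn-41, and another on chromosome X from 11605208 to 11607817, at −544 bp from ftt-2, which encodes a 14-3-3 protein. PQN-85 peaks without SMC-3 included 1 on chromosome IV from 9615353 to 9616003 within elt-1, which encodes a GATA factor of the epidermis. SMC-3 peaks without PQN-85 included 1 on chromosome V from 11313903 to 11314554 within cutl-18. No build is stated for the PQN-85 lists.

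PQN-85 stayed at most of its sites when either cohesin or WAPL-1 was depleted. The SMC-3 depletion set held 5018 PQN-85 peaks and overlapped 3865 of the control peaks (71.8%), against 6.38% for shifted sets (one-sided permutation p by shifts = 0.001). The WAPL-1 depletion set held 6713 peaks and overlapped 4425 control peaks (82.2%), against 8.30% for shifted sets (one-sided permutation p by shifts = 0.001). The peaks within pqn-41 and upstream of ftt-2 were present in all 3 sets. PQN-85 peaks present in the control only had low scores, the highest being 557 in the comparison with SMC-3 depletion, on chromosome III from 8876924 to 8877426, at −129 bp from K01F9.2. The highest-scoring peaks present in a depletion only scored far higher. The 3 highest lay on X in both comparisons, as within mom-1 from 6296018 to 6297036 with a score of 2275 in SMC-3 depletion. As a class such peaks did not score high in SMC-3 depletion. They were 65 of the 502 peaks in the upper 10% by score, but 1104 of all 5018. The site on X near F19H6.6 was among the 3 highest in both depletions. Among the upper 10% of peaks by score in SMC-3 depletion, all 39 on X without control overlap were also called in both HW04 libraries labelled no auxin, and their absence from the control set is taken up in the closing section.

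**Figure D1:**
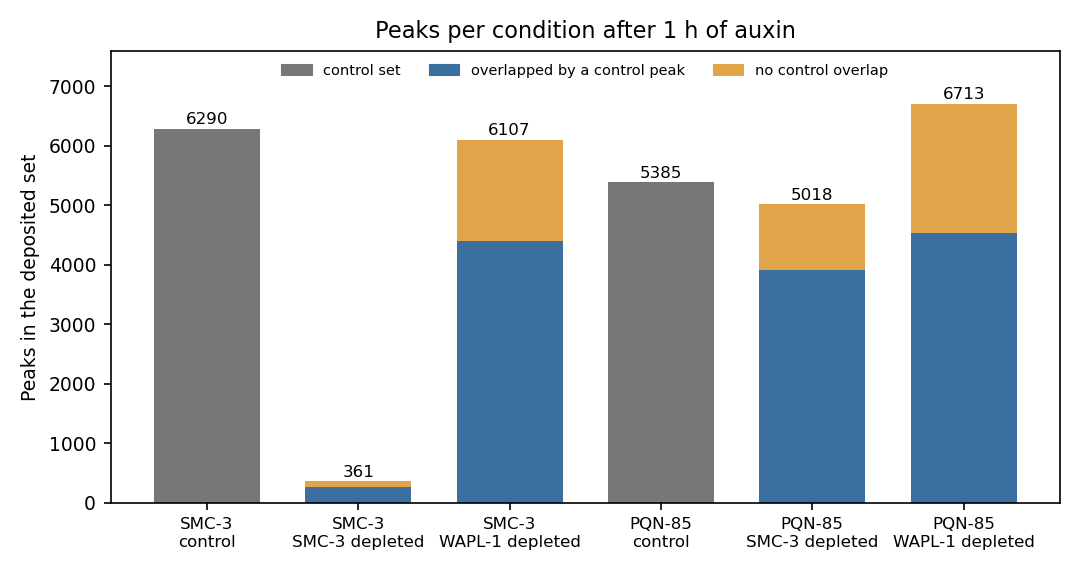
Number of peaks (vertical axis) in the authors' combined SMC-3 and PQN-85 sets for control, SMC-3 depletion and WAPL-1 depletion after 1 h of auxin. Grey bars are control sets, blue the peaks overlapped by a control peak and orange those without, and the SMC-3 set of SMC-3 depletion falls to 361 from 6290 peaks.

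The X chromosome makes up 17.7% of the assembly spanned, and its share of SMC-3 peaks lay above this in the control and depletion sets and below it in HW04 libraries labelled no auxin, which by their peak names are auxin libraries. It held 19.3% of control SMC-3 peaks (exact 95% interval 18.4 to 20.3), 19.9% in WAPL-1 depletion (18.9 to 20.9) and 23.3% in SMC-3 depletion (19.01 to 27.98). The single WAPL-1 depletion lists gave 18.6% (17.8 to 19.4) and 18.7% (17.8 to 19.6). In strain HW04 the shares were 15.3% (14.2 to 16.39) and 13.5% (12.5 to 14.6) in the libraries labelled no auxin and 17.8% (16.96 to 18.7) and 17.1% (16.3 to 17.9) in those labelled auxin.

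In strain HW04 the libraries labelled auxin had fewer PQN-85 peaks and more SMC-3 peaks than those labelled no auxin. PQN-85 lists held 6553 and 12367 peaks without auxin and 4070 and 1296 with auxin, a log2 difference of −1.97, or 0.255-fold. With 2 against 2 libraries the exact permutation p was 0.333, the smallest this design can give. The pairs by replicate number differed by −0.69 and −3.25, so the size of the PQN-85 difference rests on replicate 2. SMC-3 lists held 4305 and 4091 peaks in the libraries labelled no auxin and 7457 and 8196 in those labelled auxin, a log2 difference of 0.90, or 1.86-fold (exact permutation p = 0.333). The peak names inside these 4 SMC-3 lists state the opposite condition, and by those names the log2 difference is −0.90, so the direction for SMC-3 is not settled. Both SMC-3 lists labelled no auxin state the same extract in their peak names, so it is open whether they are separate replicates. The lists labelled no auxin overlapped 54.5% and 51.7% of control SMC-3 peaks and those labelled auxin 81.8% and 84.3%, while 86.1% and 84.9% of the former's own peaks and 68.6% and 65.9% of the latter's lay at control peaks.

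H4K20me1, a histone mark enriched on the dosage-compensated X of hermaphrodites, covered the X chromosome in all 4 HW04 libraries. X held 85.8% and 84.5% of the covered bases without auxin and 85.8% and 80.9% with auxin. The means were 85.2% ± 0.967 (SD, n = 2) and 83.4% ± 3.47 (SD, n = 2), a difference of −1.78 percentage points that is smaller than the spread between the auxin libraries (exact permutation p = 0.667). The number of H4K20me1 peaks was 5830 and 6138 without and 5723 and 6452 with auxin, a log2 difference of 0.02 (exact permutation p = 1).

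**Figure D2:**
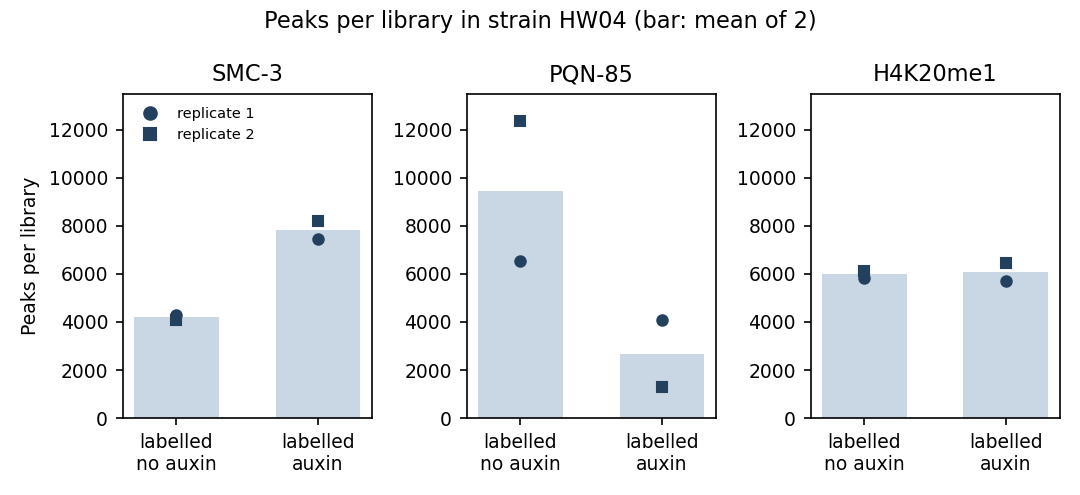
Peaks per library (vertical axis) in strain HW04 for SMC-3, PQN-85 and H4K20me1, by the auxin condition in the labels, with bars for the mean of 2 libraries and points for replicates. PQN-85 lists run from 1296 to 12367 peaks, and the SMC-3 lists carry peak names that state the opposite condition to the labels.

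After 4 h of auxin, more genes were lower than higher in the SMC-3 depletion strain compared with CA1200. Whether a given difference comes from depletion or from the strain cannot be told apart. In the authors' deposited table, 105 of 15316 tested genes had a DESeq2 adjusted p under 0.05, 34 higher and 71 lower. The largest rises among genes named by rule were swt-3, a SWEET-family sugar transporter gene, at a log2 fold change of 3.88 ± 0.27 (standard error, n = 2 per strain) and unc-119, a neuronal gene, at 2.46 ± 0.32 in the authors' deposited table. Next in the authors' deposited table came ugt-26, of the UDP-glucuronosyltransferase family, at 2.32 ± 0.46, srg-31 at 1.98 ± 0.37, the saposin-like spp-13 at 1.47 ± 0.30, the collagen col-131 at 1.37 ± 0.30, mam-3 at 1.29 ± 0.33 and the hedgehog-related wrt-1 at 1.15 ± 0.26. These 8 were all that met the rule for rises.

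Among the genes named by rule, those with the largest falls were of varied function. In the authors' deposited table, zig-2, of the immunoglobulin superfamily, fell by 4.27 and the insulin-like ins-5 fell by 3.48 on the log2 scale. The giant muscle protein gene ttn-1 changed by −2.34 ± 0.25 in the authors' deposited table, and the nuclear receptor gene nhr-74 by −2.37 ± 0.42. The collagens col-141, col-142, col-169 and col-159 stood at −2.59, −2.31, −2.27 and −2.09 in the authors' deposited table, abf-4, an antimicrobial peptide gene, at −2.62 and drd-1 at −2.15. Further called genes, chosen after their values were seen, were the TGF-beta ligand daf-7 at −1.99 ± 0.27, the insulin-like daf-28 at −1.95 ± 0.32 and lips-11 at −3.21 ± 0.54 in the authors' deposited table.

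Transcripts of the cohesin genes and of skn-1 did not pass the test. In the authors' deposited table for SMC-3 depletion, the log2 fold change was −0.23 ± 0.26 for smc-3, −0.07 ± 0.27 for wapl-1, 0.01 ± 0.27 for him-1, −0.01 ± 0.37 for scc-1, −0.06 ± 0.25 for scc-2 (PQN-85), 0.24 ± 0.30 for mau-2 and 0.06 ± 0.26 for skn-1.

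**Figure D3:**
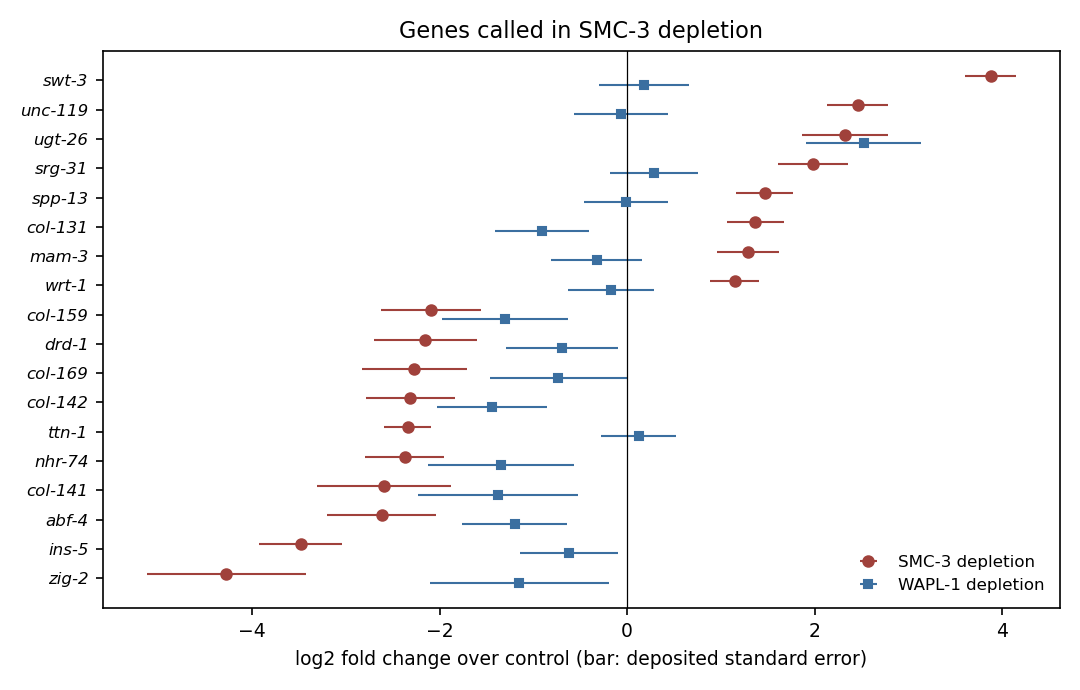
Log2 fold change over control (horizontal axis) with the deposited standard error for the 18 genes named by rule in SMC-3 depletion (red), and the same genes in WAPL-1 depletion (blue). The rise of swt-3 to 3.88 and the fall of ttn-1 to −2.34 in SMC-3 depletion have values near 0 in WAPL-1 depletion. Others moved the same way in both, such as ugt-26 at 2.52, col-142 at −1.44 and abf-4 at −1.20 in WAPL-1 depletion. The signs were opposite for unc-119, spp-13, col-131, mam-3, wrt-1 and ttn-1. The control libraries are shared, which alone can give like signs.

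Innate immunity genes were over-represented among those that fell in SMC-3 depletion. Of 28 tested members, 4 were lower and 1 higher (Fisher's exact test for lower members, p = 3.2e-04 adjusted over the lists), and 10 passed when adjusted over the list alone. In the authors' deposited table, the lysozyme gene lys-4 was at −1.86 ± 0.40, the C-type lectin gene clec-85 at −1.64 ± 0.31, cnc-2 at −1.56 ± 0.41 and sysm-1, named after its value was seen, at −1.67 ± 0.46, whereas clec-60 was at 3.55 ± 0.48. With an adjusted p under 0.01 this over-representation was lost, with 2 lower members left (Fisher's exact test, adjusted p = 0.092).

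The medians of 8 lists differed from those of expression-matched random lists in SMC-3 depletion. Lower medians were found for cytosolic heat shock (−0.86, 16 genes), innate immunity (−0.81, 28 genes), ribosomal proteins (−0.61, 61 genes), intestine (−0.48, 23 genes), body muscle (−0.45, 25 genes), germline (−0.44, 35 genes) and oxidative phosphorylation (−0.41, 34 genes). The matched random lists lay lowest for ribosomal proteins (−0.20), body muscle (−0.16) and oxidative phosphorylation (−0.13). Part of those falls is thus shared with genes of like expression. The cuticle and moulting list was higher (0.19, 44 genes). The adjusted permutation p was 8e-04 for heat shock, innate immunity, ribosomal proteins, germline and cuticle, and 0.0013, 0.0017 and 0.018 for intestine, oxidative phosphorylation and body muscle. Random lists treat genes as independent, and each strain had 2 libraries, so these p-values do not measure the spread between libraries. No heat shock member was called over all genes, while 8 of 16 were when adjusted over the list alone. In the authors' deposited table the intestinal protease genes cpr-1 and cpr-5 were called at −0.95 and −1.23. The other 12 lists had medians between −0.58 (sperm, 8 genes) and 0.06 (xenobiotic detoxification, 29 genes), with adjusted permutation p from 0.11 to 1.00. With a mean normalized count of at least 10, xenobiotic detoxification passed as well, at 0.22 over 27 genes (adjusted permutation p = 0.012), and the sperm list stood at 0.17 over 5 genes. They covered cohesin and its regulators, condensin and dosage compensation, DNA damage response, DNA replication, unfolded protein response, stage timing, pharynx, neurons, Hox factors and lipid metabolism. In the dosage compensation list, her-1, a switch gene of sex determination, was called at 3.44 ± 0.92 in the authors' deposited table.

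No gene passed the threshold in WAPL-1 depletion. In the authors' deposited table for WAPL-1, 0 of 18308 genes had a DESeq2 adjusted p under 0.05, and 73 (0.399%) had an unadjusted p under 0.05, against 1056 (5.83%) in the SMC-3 table. The smallest adjusted p was 0.793, for ugt-26, at 2.52 ± 0.62 in the authors' deposited table. In that table smc-3 was at −0.07 ± 0.39, wapl-1 at 0.22 ± 0.41, him-1 at 0.02 ± 0.40, scc-1 at 0.14 ± 0.50, scc-2 at −0.06 ± 0.39, mau-2 at 0.07 ± 0.42 and skn-1 at 0.05 ± 0.44 in the authors' deposited table. Among genes with a mean normalized count of at least 1000, the median standard error was 0.473 in the WAPL-1 table and 0.286 in the SMC-3 table. Changes of single genes were therefore harder to call in WAPL-1 depletion.

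The medians of 8 lists differed from those of random lists in WAPL-1 depletion, with 0 members called when adjusted over each list alone. Lower medians were found for cuticle and moulting (−0.45, 45 genes), heterochronic and stage timing (−0.18, 12 genes), Hox and patterning factors (−0.18, 28 genes), DNA replication and cell cycle (−0.15, 36 genes) and oxidative phosphorylation (−0.13, 34 genes). Higher medians were found for cytosolic heat shock (0.61, 16 genes), xenobiotic detoxification (0.38, 30 genes) and pharynx (0.33, 14 genes). The adjusted permutation p was 0.0024 for cuticle, Hox, DNA replication, heat shock and xenobiotic lists, 0.0047 for pharynx, 0.036 for oxidative phosphorylation and 0.041 for stage timing. Random lists treat genes as independent, and each strain had 2 libraries, so these p-values do not measure the spread between libraries. They do not show that the lists differ because of the depletion. Members with the smallest p of their lists, none of which passed, included the moulting gene mlt-10 at −1.36 ± 0.50 and the small heat shock gene hsp-16.11 at 1.26 ± 0.68 in the authors' deposited table. The other 12 lists had adjusted permutation p from 0.052 to 0.84, DNA damage response (0.20, 24 genes) being nearest to the threshold. The heat shock and the cuticle lists had opposite signs in the 2 depletions, a difference that was not tested.

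**Figure D4:**
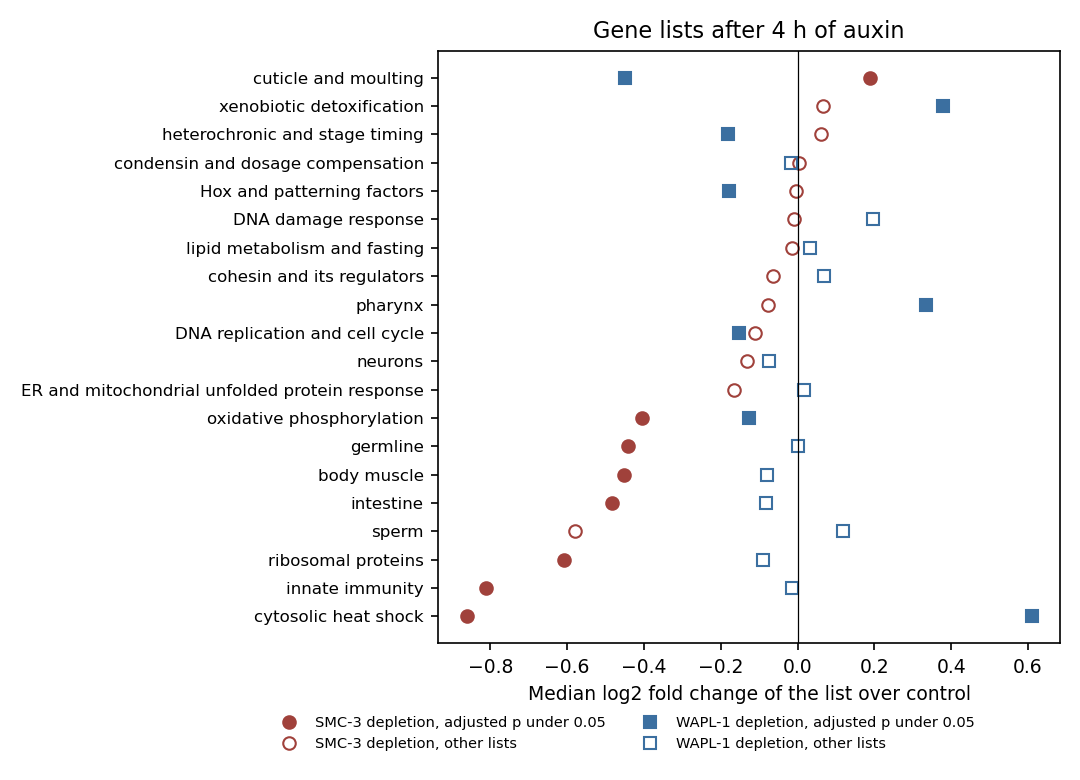
Median log2 fold change over control (horizontal axis) of the 20 gene lists in SMC-3 depletion (red circles) and WAPL-1 depletion (blue squares), with filled symbols where the list differed from expression-matched random lists. Cytosolic heat shock lies at −0.86 in SMC-3 depletion and at 0.61 in WAPL-1 depletion.

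No gene was called in both depletions. The number was 0 among 15315 genes tested in both, beside 0 expected from the counts and 0 in simulations of unchanged strains with a shared control (Fisher's exact p = 1 in each direction). With 0 genes called in WAPL-1 depletion, this test could not come out otherwise. Of the 105 genes called in SMC-3 depletion, 79 (75.2%) had the same sign in WAPL-1 depletion, where the shared control alone gave 87.1% in simulation. Across genes, which are not independent replicates, the covariance of the fold changes was 0.105, below the 0.200 simulated from the shared control. The simulation draws on the deposited standard errors, which were wide for the spread of the WAPL-1 statistics, so it is too high a reference and whether the tables are alike beyond the shared control is left open.

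X-linked genes stood slightly above autosomal genes in SMC-3 depletion. Their median log2 fold change was 0.021 over 2298 genes and that of autosomal genes −0.021 over 13018 genes, a difference of 0.042 (permutation p = 3.0e-05). The difference in means, 0.027, did not pass (permutation p = 0.058). Single autosomes also differed among themselves, with medians from −0.032 on chromosome III to −0.0019 on chromosome V. The p-value over genes does not measure this spread between chromosomes, so it does not show an effect particular to X. Called genes were not concentrated on X, with 15 of 105 (Fisher's exact p = 1). In WAPL-1 depletion the X minus autosome difference was −0.0093 (permutation p = 0.31).

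Genes near SMC-3 peaks gained in WAPL-1 depletion differed little from genes near shared peaks. The median log2 fold change was 0.069 for 1283 genes within 1000 bp of a gained peak and 0.045 for 3357 genes near shared peaks only, a difference of 0.024 (permutation p = 0.0059). With a reciprocal overlap of 50% the difference was 0.012 and did not pass (permutation p = 0.12). The build of the gene coordinates is not stated, and the plan had tied this comparison to a stated one.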

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

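The tests of the label conflict, of chance placement of neighbouring genes, of chance placement of the X peaks and of their presence in WAPL-1 depletion were chosen only after the results were seen. The other tests in this part were set before their own values were computed, but for patterns found in these data.

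By the labels of strain HW04, SMC-3 and PQN-85 peak numbers differed in opposite directions between no auxin and auxin. The log2 difference was 0.90 for SMC-3 and −1.97 for PQN-85, which lie 2.87 apart (not tested), whereas by the peak names that for SMC-3 is −0.90 and both are lower with auxin. A mislabelled sample is a candidate explanation, since all 4 SMC-3 lists carry peak names with the other auxin condition, with the input and extract numbers that the PQN-85 and H4K20me1 lists link to that condition, and none of those 8 lists conflicts with its label. Whether the labels or the peak names are wrong is not given in the sources used here, nor whether the SMC-3 lists labelled no auxin, which both state extract 784 where the other antibodies have 785 for replicate 2, come from separate extracts. A difference in depth or enrichment between groups cannot be told apart from an effect of auxin, as at least 89.7% of the peaks of each shorter list lie in the longer one, which both would give.

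Strong PQN-85 sites on X were missing from the control set. Among the upper 10% of PQN-85 peaks by score in SMC-3 depletion, 39 of 65 without control overlap lay on X (60%), against 79 of 437 with overlap (18.1%), which argues against chance placement (Fisher's exact p = 8.7e-12). A PQN-85 gain on X with SMC-3 depletion alone is argued against by WAPL-1 depletion, where 100% of the 39 sites were called as well. All 39 were also called in both HW04 libraries labelled no auxin (100%), and 94.9% carried a control SMC-3 peak, so the authors' filtering or the quality of the control set may account for the gap. A lower PQN-85 signal on X in strain CA1200 itself stays open, since signal tracks were not used here.

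Genes called in SMC-3 depletion lay side by side more often than independent placement of genes gives. There were 11 neighbouring pairs against at most 6 in 10000 expression-matched random sets (permutation p = 1e-04, the smallest they allow). The random sets take no account of neighbouring genes that are expressed together, so this test does not address that. Examples, chosen after their values were seen, in the authors' deposited table are F30A10.11 and F30A10.14 at −9.89 and −7.58, and ZK218.5, ZK218.7 and ZK218.11 at 5.58, 6.03 and 5.46. Their mean normalized counts were low, from 14.8 for ZK218.7 to 88.4 for F30A10.11. Loss of SMC-3 binding at the genes found no backing, as 0 of 19 such genes had a control SMC-3 peak within 1000 bp of their start (0%), against 25.14% of other genes (Fisher's exact p = 0.0065). The 19 genes lie in a few clusters and are not independent, so that p-value is too low. A strain variant linked to the edited smc-3 locus was tested over all called genes, not over these 19. Of called genes, 3.81% lay within 2 Mb of smc-3, against 3.87% of others (Fisher's exact p = 1). Called genes were thus not concentrated there, which does not settle whether single genes carry a linked variant. Strain variants elsewhere in the genome may contribute and were not tested.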

How the results depend on the processing

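The alternatives of the HW04 condition by peak names and of called genes without neighbours were chosen after seeing the data. All 18 alternatives of the 5 overlap comparisons kept their direction and passed the test. Of all 85 alternatives for the main results, 68 counted as unchanged. A further 11 differed by more than the set margin, 4 changed sign and 2 lost their test. Unchanged meant the same direction and side of the threshold for tested values, and a change within the set margin for counts and untested values. The HW04 tests could not pass in any setting, and WAPL-1 depletion had 0 called genes in each, so these could not change side. With the replicate block, the log2 difference of HW04 SMC-3 peaks was 0.90 (exact sign-flip p = 0.5, the smallest for 2 pairs). By the peak names it was −0.90, with and without the block. Leaving out a replicate gave 0.79 to 1.00 for SMC-3, −3.25 to −0.69 for PQN-85 and −0.0267 to 0.0720 for H4K20me1, and a stricter score gave −0.0402 for H4K20me1. The SMC-3 width ratio was 0.847 and 0.842 with the lists of replicates 3 and 4, 0.946 for mean widths and 0.957 for shared peaks. The X share of SMC-3 peaks in HW04 replicate 2 labelled auxin was 15.8% for the higher-scoring peaks. An adjusted p under 0.01 left 60 called genes in SMC-3 depletion and 0 gene lists with over-represented members, by construction stricter, and 86 were left without neighbouring genes. The X minus autosome difference in means was 0.027, and genes near gained peaks differed by 0.012 with reciprocal overlap. With a mean count of at least 10, which left 5 of 8 genes, the sperm list in SMC-3 depletion went from −0.58 to 0.17, and the xenobiotic list passed at 0.22. Values near 0 changed sign for the innate immunity list in WAPL-1 depletion (0.0459) at that count, and for him-1 (−0.0259) and skn-1 (−2.5e-04) in WAPL-1 depletion with centring. Except where stated, the cause was not tested. Without counts per library, depth limits cannot be given.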

Other observations

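The tests on the depth and the spread of the WAPL-1 table and of called genes against genes not called near SMC-3 peaks were chosen only after the result was seen. The other tests in this part were set before their own values were computed, but were not part of the plan fixed before the data.

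SMC-3 peaks called only in the control and only in WAPL-1 depletion lay in different places. Of the peaks present only in the control, 16.98% had a summit within 500 bp of a gene start, against 42.1% of shared peaks. Shifting the whole control set gave 17.5% on average, so control-only peaks showed no preference for gene starts. Whether they are sites lost on depletion or background calls was not tested. Of the peaks called only in WAPL-1 depletion, here named gained, 41.9% did (Fisher's exact p = 0.91 against shared peaks), which argues against spreading of SMC-3 away from gene starts as the source of the gained peaks. Gained peaks overlapped a control PQN-85 peak in 15.03% of cases and shared peaks in 67.5%. The median distance of gained peaks to a control PQN-85 peak was 6142 bp, against 7958 bp for shifted peaks (one-sided permutation p = 0.001), which is what spreading of SMC-3 from PQN-85 sites may give. Any tendency of peaks to lie in the same parts of the chromosomes would give it too, and the control PQN-85 set lacks strong sites on X.

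Control SMC-3 peaks that kept a counterpart after SMC-3 depletion were at strong sites, while 102 of the 361 peaks left had no control counterpart. Control peaks that kept a counterpart had a median score percentile of 92.9 among control peaks, as incomplete loss at the strongest sites may give. Of the upper 10% of control peaks 24.3% were kept, against 1.91% of the others. A lower signal or depth at a fixed cutoff would leave the highest-scoring sites as well, so these values cannot tell the 2 apart. Of the peaks left, 62.05% overlapped a control PQN-85 peak.

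PQN-85 peaks that overlapped SMC-3 in the control were kept more often on SMC-3 depletion (78.8%) than those that did not (52.0%). Within 5 classes of PQN-85 score the difference was 0.299 percentage points (permutation p = 0.75). The hypothesis that PQN-85 needs cohesin where both bind, which predicts a lower share, thus found no backing in called peaks at this time point. In the highest-scoring class the difference was 0. A fall in PQN-85 signal that stays above the calling cutoff would not show here, so the test cannot address it.

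The median fold change of genes with a control SMC-3 peak within 1000 bp of their start did not differ from that of other genes in SMC-3 depletion. Their median log2 fold change lay −0.017 from that of other genes over 3845 and 11471 genes (permutation p = 0.33 against expression-matched sets). Called genes carried such a peak less often than genes not called, at 9.52% against 25.21% (Fisher's exact p = 9.7e-05, not matched on expression). The hypothesis that loss of SMC-3 lowers genes with a peak at their start found no backing after 4 h of auxin.

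The few low p-values in WAPL-1 depletion were set against the standard errors. Among 3198 genes with a mean normalized count of at least 1000, the WAPL-1 table's standard errors were 1.62 times those of the SMC-3 table in the median, which argues against low depth as the whole cause. The deposited statistics had an SD of 0.584, below that of a standard normal, so the standard errors were wide for the fold changes. Random spread between libraries of one strain would widen the fold changes as well. Whether such spread explains the small number of low p-values is therefore left open. Counts per library, which would show that spread directly, are not given in the sources used here.

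Among libraries of one condition in strain HW04, 92.3% of the PQN-85 peaks of replicate 1 labelled no auxin lay in replicate 2 and 49.4% the other way. With auxin, 29.2% of replicate 1 lay in replicate 2 and 93.0% the other way. The PQN-85 list called on averaged WAPL-1 depletion libraries held 11303 peaks and overlapped 96.5% of control PQN-85 peaks.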
